A study of Mus musculus with 7 samples.

How the data were processed

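RNA was measured in 7 subcutaneous tumours, 3 from vehicle-treated and 4 from PEGPH20-treated C57BL/6 mice, and each tumour gave 1 library. Per the labels' protocols, libraries were made from 200 ng of total RNA with a 3′ mRNA kit (Lexogen QuantSeq FWD, with optional molecular identifiers) and sequenced from a single end for 75 nt on an Illumina NextSeq sequencer. Whether the molecular identifiers were used to collapse reads was not given in the sources used here. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the normalization tool were not given in the sources used here. Because the kit reads the 3′ end of transcripts, a value covers the end of a gene and says nothing of its other exons.

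The deposited table held 47643 gene rows and 7 columns, each with 1 signal value per gene. From the values themselves, the authors' signal was a read count divided by 1 size factor per library. In each column 100% of the values above 0 were whole multiples of the column's smallest value, with a tolerance of 0.01. Whole reads were therefore recovered by dividing each column by that smallest value. The recovered totals were 4204388 to 4304108 reads in the vehicle libraries and 4582238 to 6703775 in the PEGPH20 libraries. The authors' size factors were 1.264 to 1.35 times the DESeq2 size factors recomputed on these 7 libraries. The deposited values are called normalised read counts here. Symbols were found for 47224 of the gene identifiers in a mouse gene name table, and coordinates come from GENCODE release M21, which uses the same build.

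The plan, fixed before the data were examined, assumed raw counts and named the edgeR quasi-likelihood test. The values were not raw counts, so the test named for that case was used. It was limma on log2(value + 1) with an intensity trend, for genes with a mean value of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 17132 genes in all 7 libraries with treatment as the only term. A fold change is thus on the log2(value + 1) scale, which understates the change of genes with low values. Level of a gene list in a library is the mean log2(value + 1) of its tested members, in place of the log2 CPM that the plan named. The edgeR quasi-likelihood test on the recovered reads (TMM scaling, filterByExpr) was added as an alternative after the values were seen, and it called 0 genes. The p-values of single genes measure the spread between these tumours. Libraries of the same group differed well beyond sampling noise, with a chi-square per degree of freedom of 6.59 to 16.3, so none was a copy of another.

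In all, 38 gene lists were fixed before the data were examined: 15 of programs, 20 of cell types and 3 of sample quality. Lists were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. The preset takes a list's genes as nearly independent, so its p-values do not measure how a list's level varies between tumours. The estimated correlation was over 0.1 in 30 of the 38 lists, and at most 0.863. The fry test asked whether a list's genes moved one way. An exact permutation test, two-sided, set the difference of list levels against all 35 splits of the 7 libraries into 3 and 4, where the smallest possible p is 0.0286. Members were also adjusted over the list alone.

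Named genes were chosen by a rule fixed before the data were examined. It names Prkci and Prkcz first. It then takes genes past the threshold, of which there were 0, and so in their place the 8 genes per direction with the smallest unadjusted p. Those needed a mean of at least 5 CPM and no overlap between the groups, with predicted gene models, clone names, pseudogenes and immunoglobulin or T cell receptor segments left out. Up to 2 members per list with the smallest p follow, and last a fixed set of hyaluronan, fibroblast, epithelial and T cell genes. A gene that met more than 1 part counts under each.

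Each alternative in limma changed 1 choice, with 1 exception. The removal of muscle, skin, adipocyte and red blood cell list genes also replaced the authors' size factors by TMM scaling. DESeq2, the edgeR settings and voom changed the test together with the scaling and the filter, with 13079 genes kept in edgeR and voom. The alternatives were DESeq2 with its own size factors, DESeq2 or upper-quartile scaling in edgeR, voom with sample weights, no filter beyond 1 read over all libraries, at least 5 CPM in 3 libraries, a pseudocount of 0.1, an adjusted p under 0.1, 1 surrogate variable from sva, the removal of muscle, skin, adipocyte and red blood cell list genes, and each library left out in turn. Alternatives added after seeing the data were edgeR itself, DESeq2 and upper-quartile scaling in limma, the removal of the 3 libraries richest in muscle transcripts, and the mean of the pan-fibroblast list as a covariate. Those 3 libraries were vehicle replicate 16 and PEGPH20 replicates 11 and 37, with muscle list levels of 8.09, 5.63 and 4.57. The libraries kept had levels of 2.73 and 4.02 with vehicle and 1.63 and 1.55 with PEGPH20, so this setting did not even out muscle transcripts. The limma steps were tested on simulated counts for these libraries, with 200 changed genes in each of 5 runs and 17010 genes tested on average. In them limma found 65% of 2-fold and 95% of 4-fold changes, and 5.75% of its calls were false. The 200 genes were all of at least 5 CPM, and the simulated counts were scaled by TMM. Each gene was drawn independently, without structure shared within a library, so these rates need not hold for the real libraries. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0.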

Results

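Gene expression was measured in subcutaneous flank tumours grown from MTO cells, as the labels name them, of the genotype sgPrkci/Prkcz. Prkci and Prkcz encode the atypical protein kinase C isoforms. The cells were injected in 30% Matrigel into C57BL/6 mice aged 7 weeks. From day 15 the mice received vehicle or 0.0375 mg/kg PEGPH20, a pegylated hyaluronidase that breaks down the matrix polysaccharide hyaluronan, 2 times a week for 3 weeks. There were 3 vehicle tumours (replicates 14, 16 and 33) and 4 PEGPH20 tumours (replicates 11, 12, 19 and 37). The recovered depth was 4204388 to 4304108 reads per vehicle library and 4582238 to 6703775 per PEGPH20 library. Mitochondrial transcripts made up 10.97% to 12.28% of the reads. The only comparison the design implies is PEGPH20 against vehicle, which asks how the tumours' expression differed after treatment with the enzyme; no value here measures hyaluronan itself.

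Prkci (ENSMUSG00000037643, GRCm38 chromosome 3, 30995747 to 31052959) had 221 ± 43.1 normalised read counts with vehicle (SD, n = 3) and 184 ± 28.1 with PEGPH20 (SD, n = 4). Per library, Prkci was 214, 267 and 182 in vehicle replicates 14, 16 and 33, and 203, 144, 183 and 204 in PEGPH20 replicates 11, 12, 19 and 37. Prkcz (ENSMUSG00000029053, chromosome 4, 155260129 to 155361361) had 10.0 ± 3.58 and 14.4 ± 5.82. Its libraries read 13.9, 9.19 and 6.94 with vehicle and 21.5, 8.96, 10.5 and 16.8 with PEGPH20. Both groups carry the same edit, and 3′ reads need not cover the edited part, so these values check no label.

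No single gene passed the threshold. By limma 0 of 17132 genes were called, with a smallest adjusted p of 0.218, while 2083 had an unadjusted p under 0.05 where chance gives 857. The edgeR test on the recovered reads called 0 of 13079 genes, with 1704 at an unadjusted p under 0.05, and DESeq2 called 64, of which 28 were higher and 36 lower with PEGPH20. Of the 2083 genes, 62.3% were higher with PEGPH20, but that share was 50.4% with DESeq2 size factors, 49.3% with upper-quartile scaling and 48% in edgeR. At 5 CPM or more, 1593 of 11156 genes had no overlap in CPM between the groups, which is 14.3% where chance gives 5.71%. Of these, 1218 were higher and 375 lower with PEGPH20. CPM scales by the library total alone, and neither the 14.3% nor this division was computed under another scaling or for another grouping of the libraries.

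Of the 16 genes of smallest p, 8 had larger values under PEGPH20. Ociad1 (chromosome 5, 73292784 to 73314069) had 438 ± 18.4 normalised read counts with vehicle and 743 ± 77.3 with PEGPH20, a log2 difference of 0.76 ± 0.10 (SE), with limma's adjusted p = 0.218. An antisense gene model overlaps its exons, and strand use in the counting was not given in the sources used here, so its value is uncertain. Klf5, a transcription factor of proliferating intestinal epithelium, read 1099 ± 66.1 and 1635 ± 123. Cldn7, a tight junction protein, read 257 ± 20.6 and 396 ± 30.4. Bst2, an interferon-induced membrane protein that tethers virions, read 173 ± 57.9 and 470 ± 142, a log2 difference of 1.44 ± 0.26. Dirc2 had a log2 difference of 0.57 ± 0.10 and Reep4 0.55 ± 0.10. Npm3, a nucleolar chaperone (0.94 ± 0.16), and Nfix (0.61 ± 0.10) also have antisense genes across their exons and are uncertain.

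The other 8 had smaller values under PEGPH20. Fbln5, an elastic fibre protein (chromosome 12, 101746565 to 101819055), read 98.7 ± 5.30 with vehicle and 50.3 ± 2.61 with PEGPH20, a log2 difference of -0.96 ± 0.13 with limma's adjusted p = 0.218. Tmsb4x, which binds actin monomers, read 6630 ± 513 and 4066 ± 415, and Tubb2b, a beta-tubulin, read 295 ± 67.4 and 118 ± 33.6. The desmosome genes Jup and Dsp had log2 differences of -0.69 ± 0.11 and -0.60 ± 0.11, the latter uncertain because an antisense gene overlaps its exons. Sat1, an enzyme of polyamine breakdown, had -0.70 ± 0.10, Tspan14 -0.47 ± 0.08 and Enc1 -0.50 ± 0.10. None of the 16 genes passed limma's threshold with all 7 libraries and no covariate, and their direction was the same under every alternative run. All 16 passed in limma with 1 surrogate variable (from Bst2, adjusted p = 0.00105, to Enc1, adjusted p = 0.0258) and in DESeq2 (from Tmsb4x, adjusted p = 1.64e-07, to Dirc2, adjusted p = 0.0315). The 16 genes were picked for small p in these same 7 libraries, so neither these passes nor the stable direction is separate support. The surrogate variable was estimated from the same values with treatment kept in the model. DESeq2 called up to 711 genes in other splits of the libraries.

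**Figure D1:**
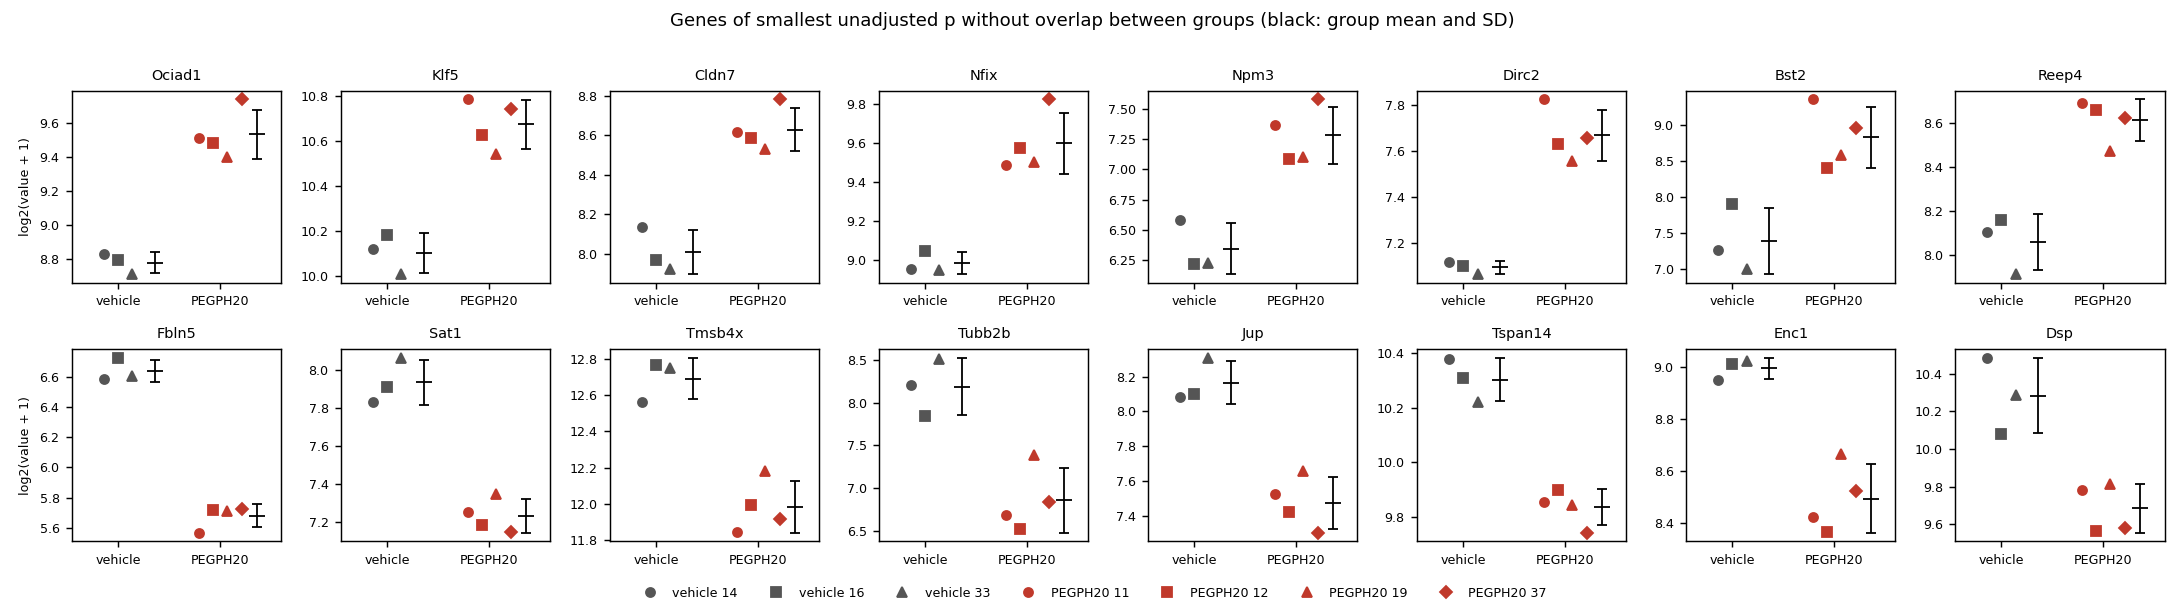
Level of the 8 genes per direction with the smallest unadjusted p and no overlap between the groups, as log2(value + 1) on the vertical axis for each of 3 vehicle (grey) and 4 PEGPH20 (red) libraries. Black marks give the group mean and SD, each panel has its own range, and Bst2 differs by 1.44 and Tubb2b by -1.32 between the group means.

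Fibroblast and matrix lists were lower with PEGPH20 as sets. Of 20 pan-fibroblast markers, 18 had smaller values with PEGPH20, and the list mean was 8.79 ± 0.55 with vehicle (SD, n = 3) and 8.12 ± 0.47 with PEGPH20 (SD, n = 4; camera adjusted p = 6.36e-07). The same held for 31 of 34 collagens, cross-linkers and matrix proteins (mean log2 difference -0.56, adjusted p = 3.67e-09), 15 of 16 myofibroblast and contractile genes (-0.69, adjusted p = 3.49e-06) and 21 of 21 genes of the epithelial-mesenchymal transition list (-0.59, adjusted p = 7.65e-07). All 4 lists had an adjusted p = 0.644 with an estimated correlation, and an exact permutation adjusted p = 0.575. The smallest possible permutation p before adjustment is 0.0286. An adjusted value under 0.05 would have needed many lists at that floor, so the 0.575 decides nothing. Unadjusted, the exact permutation p was 0.257 for the pan-fibroblast and matrix lists. It was 0.114 for the contractile list and 0.143 for the epithelial-mesenchymal transition list. Lum, a collagen-binding proteoglycan, read 97.7 ± 67.6 with vehicle and 24.0 ± 9.18 with PEGPH20. Acta2, the smooth muscle actin of myofibroblasts, read 463 ± 234 and 247 ± 91.9, Col1a1 7287 ± 4536 and 4219 ± 1974, and Vim, an intermediate filament of mesenchymal cells, 1545 ± 268 and 1058 ± 202. Pcolce, an enhancer of procollagen processing, went the other way at 380 ± 23.9 and 495 ± 59.4, but it shares exons with Fbxo24 on the same strand and is uncertain. Vehicle replicate 33 had the highest pan-fibroblast level, 9.42 against 7.63 to 8.59 in the other libraries. Without it the differences shrank to -0.35 for the pan-fibroblast list, -0.24 for the matrix list, -0.38 for the contractile list and -0.36 for the epithelial-mesenchymal transition list. All 4 were still called by camera with the preset correlation. That carries little weight, since the same test called 6 to 28 lists in every split of the 7 libraries into 3 and 4. Without vehicle replicate 16 the epithelial-mesenchymal transition list differed by -0.95. Single genes also shifted without vehicle replicate 33: Col1a1 differed by -0.28 in place of -0.75 and Acta2 by -0.48 in place of -0.87.

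Vascular, inflammatory fibroblast and signalling lists were lower as well. Pericyte markers had smaller values with PEGPH20 in 12 of 12 members (mean log2 difference -0.66, adjusted p = 6.91e-06, and adjusted p = 0.644 with an estimated correlation), among them Notch3, uncertain for an antisense gene across its exons, at 68.3 ± 15.3 and 45.8 ± 3.85. Endothelial markers did so in 21 of 24 (-0.29, adjusted p = 0.000443, and adjusted p = 0.644 with an estimated correlation), with Esam, an endothelial adhesion molecule, at 86.7 ± 14.8 and 58.9 ± 13.4. The inflammatory fibroblast list had 13 of 21 (-0.37, adjusted p = 0.0446, and adjusted p = 0.644 with an estimated correlation), with Pdpn at 187 ± 40.5 and 101 ± 31.5 and the protease gene Mmp3 at 371 ± 337 and 68.5 ± 41.7. Mmp3 read 745 in vehicle replicate 14, and its log2 difference was -2.10 with all libraries and -1.36 without that replicate. Fetal-like and YAP targets had 15 of 24 (-0.17, adjusted p = 0.0314, and adjusted p = 0.644 with an estimated correlation), with Ccn1 at 175 ± 65.1 and 81.2 ± 15.8. TGF-beta response genes had 18 of 22 (-0.20, adjusted p = 0.0117, and adjusted p = 0.723 with an estimated correlation), and 4 members passed when adjusted over the list alone (0 over all genes), of which Ski, Tgif1 and Bhlhe40 fell and Id1 rose. The inflammatory fibroblast call was lost in 10 of 22 settings. Without vehicle replicate 14 (-0.11, adjusted p = 0.504) and PEGPH20 replicate 37 (-0.24, 0.114) the difference shrank. It hardly moved without PEGPH20 replicate 19 (-0.37, 0.103), with a pseudocount of 0.1 (-0.33, 0.0525) and with DESeq2 (-0.40, 0.0693) or upper-quartile (-0.41, 0.0760) scaling. The same held without the muscle, keratinocyte, adipocyte and red blood cell list genes (-0.40, 0.0677), a setting that also used TMM scaling. Over the 22 settings the difference reached -0.67 at its lowest. The TGF-beta call was lost without vehicle replicates 14 (-0.14, adjusted p = 0.178) or 33 (-0.05, 0.356) or PEGPH20 replicate 37 (-0.11, 0.0862). The fetal-like call was lost without vehicle replicate 14 (-0.06, adjusted p = 0.4885) or PEGPH20 replicates 11 (-0.16, 0.05004) or 37 (-0.14, 0.0537). Without vehicle replicate 16 these 3 lists differed more, by -0.56, -0.40 and -0.29. The endothelial difference was -0.17 without PEGPH20 replicate 37 and -0.02 without the 3 muscle-rich libraries, which ended its call (adjusted p = 0.253), and the pericyte difference was -0.37 without those 3.

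The hyaluronan list, of synthesis, breakdown and binding genes, had smaller values with PEGPH20 in 19 of 24 tested members (mean log2 difference -0.17, camera adjusted p = 0.00642). It had an adjusted p = 0.644 with an estimated correlation, and the camera call was lost without vehicle replicate 14 (-0.12, adjusted p = 0.0524) and without the 3 muscle-rich libraries (-0.05, 0.0800). The difference was -0.08 without vehicle replicate 33 and -0.08 without PEGPH20 replicate 37, both still called. Cd44, the main hyaluronan receptor (chromosome 2, 102811141 to 102901665), read 7072 ± 201 normalised read counts with vehicle and 5553 ± 168 with PEGPH20, without overlap, a log2 difference of -0.35 ± 0.09 with limma's adjusted p = 0.302 and DESeq2's adjusted p = 0.000414. Cemip2, a cell-surface protein linked to hyaluronan breakdown, read 2171 ± 627 and 1249 ± 350. The synthase Has2 read 56.2 ± 15.3 and 39.4 ± 19.99, and Has3 8.78 ± 4.24 and 4.09 ± 1.84, and both, like Cemip2, are uncertain because an antisense gene overlaps their exons. Has1 had 9 reads over all 7 libraries and was not tested. The hyaluronidases Hyal1 (94.7 ± 17.0 and 83.0 ± 17.5) and Hyal2 (253 ± 46.2 and 221 ± 26.3) overlapped between groups, and Hyal1 shares exons with Hyal3 and Naa80 on the same strand. Cemip read 20.4 ± 14.9 and 11.7 ± 3.95, and Lyve1, the lymphatic hyaluronan receptor, 18.3 ± 13.0 and 23.03 ± 12.8. Cemip2, Has2, Has3, Cemip and Lyve1 overlapped between groups as well.

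Proliferation and ribosome lists were higher with PEGPH20 as sets. Of 37 cell cycle genes 34 had larger values (mean log2 difference 0.35, camera adjusted p = 7.93e-08), as did 26 of 26 MYC and ribosome biogenesis genes (0.32, adjusted p = 1.28e-06) and 41 of 44 ribosomal protein genes (0.22, adjusted p = 7.50e-07). With an estimated correlation the first pair had an adjusted p = 0.644 and the ribosomal list an adjusted p = 0.723 with an estimated correlation. Mcm7, a subunit of the replicative helicase, read 278 ± 14.7 with vehicle and 368 ± 9.37 with PEGPH20 and was the 1 cell cycle member to pass when adjusted over the list alone, with 0 over all genes. Its exons overlap Ap4m1 and Cops6 on the other strand, so its value is uncertain. Rrm2, which makes deoxynucleotides, read 211 ± 59.5 and 355 ± 86.5, and Rps20, which shares exons with a gene model on the same strand and is uncertain, read 4300 ± 641 and 6193 ± 726. The cell cycle level of vehicle replicate 16, 8.04, lay within the PEGPH20 range of 7.82 to 8.08, while replicates 14 and 33 had 7.43 and 7.34. Without vehicle replicate 33 the differences were 0.21 for the cell cycle, 0.21 for the MYC and 0.09 for the ribosomal list, of which the last was no longer called (adjusted p = 0.0652). Without vehicle replicate 16 they were 0.57, 0.48 and 0.34, and without the 3 muscle-rich libraries the cell cycle difference was 0.52. With the pan-fibroblast mean as a covariate the cell cycle (0.15, camera adjusted p = 0.069) and MYC (0.12, 0.239) calls were lost.

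Interferon and antigen presentation lists were also higher with PEGPH20. The type I interferon list had larger values in 26 of 29 genes (mean log2 difference 0.44, camera adjusted p = 0.000105), the interferon-gamma list in 22 of 24 (0.47, adjusted p = 0.000272) and the MHC list in 23 of 24 (0.28, adjusted p = 0.0198). These became adjusted p = 0.723 with an estimated correlation for both interferon lists and adjusted p = 0.809 with an estimated correlation for the MHC list. Isg15, a ubiquitin-like interferon product, read 123 ± 21.4 and 227 ± 38.4, and it and Bst2 passed when adjusted over the list alone, with 0 over all genes. Ido1, a tryptophan-degrading enzyme, read 22.8 ± 10.0 and 53.4 ± 23.4. Tgtp1 and H2-Q4 belong to families with near-identical copies, so their values (18.3 ± 4.64 and 37.4 ± 12.3, 367 ± 148 and 635 ± 134) are uncertain. Without vehicle replicate 33 all 3 calls were lost and the differences shrank to 0.18 (adjusted p = 0.0824), 0.26 (0.0744) and 0.016 (0.959). Without PEGPH20 replicate 11 the interferon-gamma (0.25, adjusted p = 0.05004) and MHC (0.15, 0.205) calls were lost. The MHC call was also lost without vehicle replicate 14 (0.20, adjusted p = 0.206) and, with its difference unchanged at 0.28, with the filter of 5 CPM (0.0578), while the difference was 0.62 without vehicle replicate 16 and 0.52 without the 3 muscle-rich libraries.

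**Figure D2:**
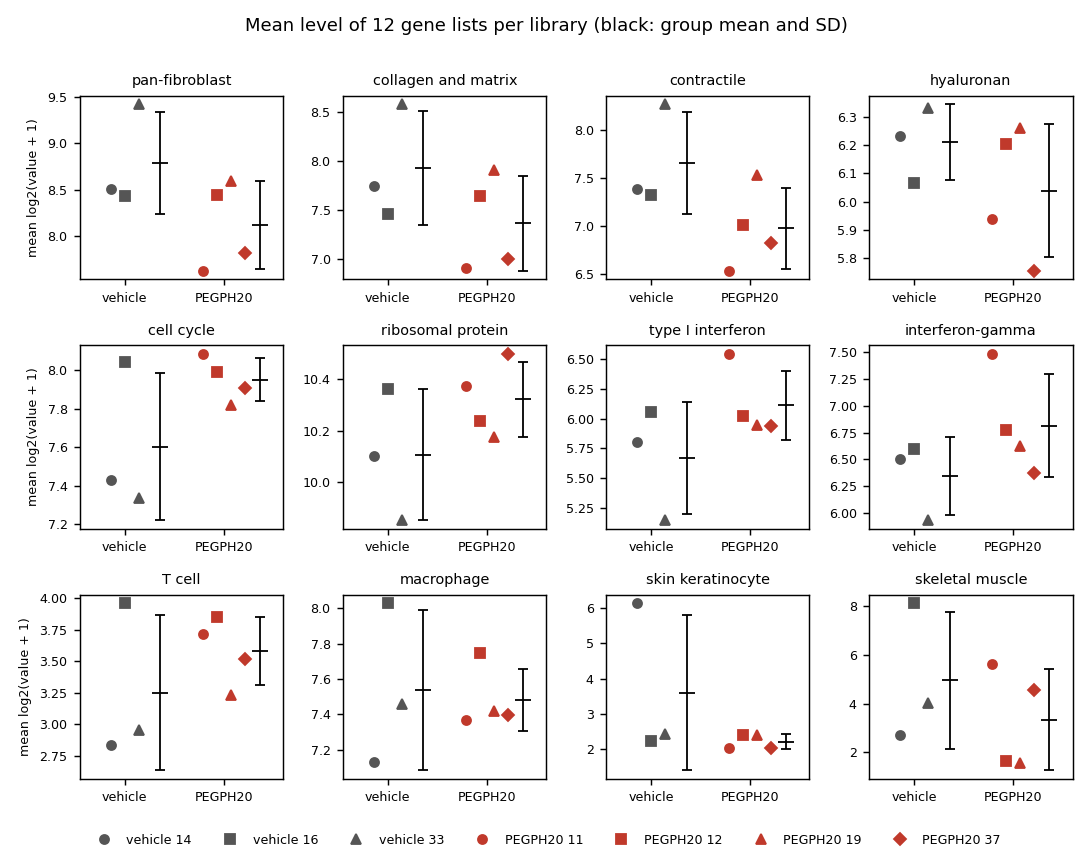
Mean log2(value + 1) of the tested members of 12 gene lists on the vertical axis, for each of 3 vehicle (grey) and 4 PEGPH20 (red) libraries, with the group mean and SD in black and a separate range per panel. The groups overlap in every panel; vehicle replicate 33 is highest for fibroblast genes (9.42), replicate 14 for keratinocyte genes (6.13) and replicate 16 for muscle genes (8.09).

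Camera with the preset correlation and no covariate called no immune cell list in limma with all 7 libraries. The T cell list differed by 0.33 on the log2 scale (adjusted p = 0.107), the CD8 and cytotoxic list by 0.32 (adjusted p = 0.182), the checkpoint and regulatory T cell list by 0.28 (adjusted p = 0.535) and the B cell and plasma cell list by 0.36 (adjusted p = 0.445). Cd8a, the CD8 coreceptor, read 4.45 ± 1.02 and 7.35 ± 3.72, and Trbc1, a T cell receptor constant segment, 7.73 ± 2.85 and 14.4 ± 1.75. Macrophage (-0.06, adjusted p = 0.299), neutrophil (-0.11, adjusted p = 0.333), dendritic cell (0.16, adjusted p = 0.960) and mast cell (-0.50, adjusted p = 0.0775) lists were not called either. The T cell list was called higher in 5 of 22 other settings: without vehicle replicate 16, which had the highest T cell level of 3.96 (0.68, adjusted p = 0.00145), without PEGPH20 replicate 19 (0.44, 0.0260), without the 3 muscle-rich libraries (0.65, 0.00265), with 1 surrogate variable (0.43, 0.0295) and with sample weights (0.55, 0.0198), but it was 0.12 without vehicle replicate 14. The mast cell list was called lower in 5 of 21 (-0.77 to -0.59), but it was -0.30 without vehicle replicate 14. Without vehicle replicate 16 the CD8, checkpoint and B cell differences were 0.52, 0.48 and 0.89. The CD8 difference was 0.18 and the B cell difference -0.32 without vehicle replicate 14, and the checkpoint difference was 0.08 without vehicle replicate 33. Without vehicle replicate 14 the macrophage list was called at -0.26 (adjusted p = 0.000352).

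The epithelial tumour cell list was not shifted as a set (adjusted p = 0.836), and its members went both ways, 12 larger and 13 smaller with PEGPH20. Adjusted over the list alone, 6 members passed. Cldn7, Prom1 and Lgals4 rose, with log2 differences of 0.62, 1.35 and 1.92, while Epcam, Elf3 and Cldn4 fell, with -0.37, -0.56 and -0.49, Elf3 with an antisense gene across its exons and thus uncertain. Adjusted over all genes, 0 of the 6 passed in limma. Epcam, an epithelial adhesion molecule, read 6109 ± 362 with vehicle and 4729 ± 463 with PEGPH20. The intestinal stem cell and WNT target list differed by 0.20 (adjusted p = 0.625), with Nkd1, a WNT feedback inhibitor, at 143 ± 61.4 and 418 ± 227. The list difference was 0.08 without PEGPH20 replicate 37 and 0.30 without PEGPH20 replicate 12. Secretory and absorptive genes (0.36, adjusted p = 0.535, but 0.013 without vehicle replicate 33 and 0.79 without vehicle replicate 16), hypoxia and glycolysis (-0.02, adjusted p = 0.957), the unfolded protein response (0.11, adjusted p = 0.625) and p53 targets (0.03, adjusted p = 0.883) were not called. The unfolded protein difference was 0.03 without vehicle replicate 33 and 0.18 without vehicle replicate 16. The hypoxia list was called lower without vehicle replicate 16 (-0.16, adjusted p = 0.0242) and without the 3 muscle-rich libraries (-0.12, 0.00777), and higher without vehicle replicate 14 (0.12, 0.0271). For the epithelial, dendritic cell and p53 lists the mean difference was above 0 while camera placed them lower than other genes, and for the hypoxia list the median was above 0 and the mean below.

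Keratinocyte and muscle transcripts differed strongly between single tumours. The skin keratinocyte list was called lower with PEGPH20 (mean log2 difference -1.38, adjusted p = 5.01e-07, and adjusted p = 0.644 with an estimated correlation), and vehicle replicate 14 had a level of 6.13 against 2.03 to 2.42 in the other 6 libraries. Without it the difference was -0.21 (adjusted p = 0.180). The skeletal muscle list was called lower (-1.60, adjusted p = 8.00e-05, and adjusted p = 0.723 with an estimated correlation), with levels of 8.09 in vehicle replicate 16 and 5.63 in PEGPH20 replicate 11 against 1.55 in PEGPH20 replicate 19. Without vehicle replicate 16 the difference was -0.07 (adjusted p = 0.679), and with sample weights the call was also lost (-1.30, adjusted p = 0.07845). It was -2.71 without vehicle replicate 14, -1.03 without PEGPH20 replicate 12 and -1.004 without PEGPH20 replicate 19. The lowest muscle list difference over the 21 settings was -3.70. Adipocyte (0.51, adjusted p = 0.0724), red blood cell (0.16, adjusted p = 0.535), Schwann and nerve (-0.11, adjusted p = 0.445) and lymphatic endothelial (0.06, adjusted p = 0.919) lists were not called, though the adipocyte list was called higher in 6 of 21 other settings (0.53 to 0.89) and was 0.28 without vehicle replicate 33. With each library left out, the red blood cell difference ranged from 0.07 to 0.28 and the Schwann difference from -0.24 to -0.006. Of the sample quality lists beside the ribosomal one, immediate early and heat shock genes differed by -0.19 (adjusted p = 0.0690) and were called lower in 11 of 22 other settings (-0.30 to -0.20), among them edgeR (-0.27, adjusted p = 0.0367), sample weights (-0.30, 0.0114) and 1 surrogate variable (-0.20, 0.0494), but the difference was -0.06 without vehicle replicate 14. Mitochondrially encoded genes differed by -0.03 (adjusted p = 0.437).

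By camera with a preset correlation 18 of 38 lists were called, 6 higher and 12 lower with PEGPH20. None of the 18 held with an estimated correlation (smallest adjusted p = 0.644) or by fry (smallest adjusted p = 0.566), and 0 of 38 list levels had an exact permutation p under 0.05, where the smallest possible over 35 splits is 0.0286. With the pan-fibroblast mean as a covariate 4 lists were called, all lower: keratinocyte, muscle, mast cell and immediate early genes.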

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

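In the PEGPH20 group, 7 of 140 list levels, named genes and library measures had 1 library far from the other 3, which is 5% and the share chance gives. The vehicle group of 3 was too small for this test. Leaving out each library was planned, but the explanation by 1 library alone was put forward only after the result was seen.

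PEGPH20 replicate 11 stood apart for the type I interferon list, at 6.55 against 5.93 to 6.02 in the other PEGPH20 libraries (gap 0.86 of the range), and for Fbln5, at 46.4 against 51.4 to 51.8 (0.92). PEGPH20 replicate 12 stood apart for the macrophage list, at 7.75 against 7.37 to 7.42 (0.859), for Mmp3, at 131 against 45.2 to 52.5 (0.916), and for Ighm, at 776 against 43.8 to 99.4 (0.924). PEGPH20 replicate 37 stood apart for Itgav, uncertain for an antisense gene across its exons, at 183 against 257 to 261 (0.945), and for Cad, at 234 against 177 to 183 (0.892).

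The higher interferon lists with PEGPH20 were weighed against that library. Without PEGPH20 replicate 11 the interferon-gamma list had a camera adjusted p of 0.05004 while the type I list kept its call, so the library alone could not be separated from a wider difference. Neither call was robust to every library: without vehicle replicate 33 the camera adjusted p was 0.0824 for type I and 0.0744 for interferon-gamma. A larger share of immune cells may also raise interferon genes. The type I list less the mean of the macrophage, T cell and dendritic cell lists differed by 0.301 between the groups, but vehicle replicate 14, at 1.07, lay above PEGPH20 replicate 12, at 0.54, which leaves that explanation open. With the pan-fibroblast mean as a covariate the type I difference was 0.03 and the interferon-gamma difference 0.11 (camera adjusted p = 0.876 for each). That covariate differs between the groups, so it can remove a treatment difference and does not decide. An effect of PEGPH20 on interferon signalling also stays open.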

How the results depend on the processing

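The absence of called genes held in limma and edgeR under the planned scalings, filters, pseudocount and the looser threshold, but not with 1 surrogate variable, which gave 522 genes (253 higher, 269 lower), or DESeq2, which gave 64 (28 higher, 36 lower); the cause was not tested. With each library left out the count was 0 to 3 genes, all higher, and the 3 without vehicle replicate 16 were H2-M2, Psat1 and Tmem158, named after their values were seen. The 18 called lists became 14 to 21 with each library left out (2 to 8 higher, the 2 without vehicle replicate 33) and 0 with an estimated correlation or by fry, 0 in both directions. With the pan-fibroblast mean as a covariate, chosen after seeing the data, 4 lists were called, 0 higher and 4 lower; the covariate itself differs between groups, so it can remove a treatment difference. No paired analysis was possible because the groups share no replicate numbers. Depth limits genes of few reads, such as Has1.

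Of the 99 named genes, 92 kept their direction in every setting that tested them, at most 21, and of the 18 called lists 13 did, in at most 22 settings. That covariate turned the sign of the hyaluronan (0.046), matrix (0.12), TGF-beta (0.11), stem cell (-0.054), dendritic (-0.081), MHC (-0.12), lymphatic (-0.24), unfolded protein (-0.022) and ribosomal (-0.0091) lists, and of Prkcz (-0.13), Spdef (-0.049), Has2 (0.073), Hyal1 (0.038), Cemip (0.28), Lyve1 (-0.47) and Col1a1 (0.27). Without the 3 muscle-rich libraries, also chosen after seeing the data, macrophage (0.29), lymphatic (-0.13) and Prkcz (-0.026) values turned. In edgeR the checkpoint (-0.0067), lymphatic (-0.0740) and p53 (-0.0162) lists turned, with DESeq2 size factors there -0.0069, -0.0737 and -0.0158, and the lymphatic list with upper-quartile scaling (-0.058). In limma the p53 list was -0.0016 with DESeq2 size factors and -0.0074 with upper-quartile scaling. Sample weights gave checkpoint -0.0051, macrophage 0.061, p53 -0.0089 and red blood cell -0.040. The 5 CPM filter gave checkpoint -0.038 and dendritic -0.030. The cause of these turns was not tested.

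With each library left out, lists that turned ranged from -0.32 to 0.89 (B cell), -0.26 to 0.19 (macrophage), -0.28 to 0.16 (neutrophil), -0.067 to 0.50 (dendritic), -0.16 to 0.18 (lymphatic), -0.16 to 0.12 (hypoxia), -0.0016 to 0.079 (p53) and -0.054 to 0.012 (mitochondrial), and the genes Cemip from -1.27 to 0.14 and Lyve1 from -0.0029 to 0.91. Of the 20 lists not called, 6 were called under at least 1 other setting.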

Other observations

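Of the 64 genes that DESeq2 called, Tff2 and Olfm5 are named here after their values were seen, and no list of such genes was tested. Tff2, a mucosal trefoil peptide, read 135 ± 70.1 normalised read counts with vehicle (SD, n = 3) and 399 ± 132 with PEGPH20 (SD, n = 4), with DESeq2's adjusted p = 0.0147 and limma's adjusted p = 0.302. Olfm5 read 4.48 ± 2.81 and 48.3 ± 55.1, with a large spread within the PEGPH20 group. Adjusted over the lists alone, Asns, which makes asparagine, rose by 0.82 on the log2 scale, and the adipocyte genes Cfd and Cidea by 2.82 and 0.99, while 0 of them passed over all genes in limma. Cfd read 1.79 ± 0.95 with vehicle, near the floor, and 26.3 ± 21.5 with PEGPH20, where replicate 37 had 2.92. Gm42418, a gene model that overlaps ribosomal RNA sequence, read 171571 ± 27356 with vehicle and 109402 ± 25748 with PEGPH20. The Y-linked gene Ddx3y ranged from 125 in PEGPH20 replicate 37 to 381 in PEGPH20 replicate 12, and Uty from 38.1 to 147.

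The tests over all splits for limma and camera and the correlations were chosen after the result was seen. Leaving out vehicle replicate 14 was planned, but the explanation by that library alone was put forward only after the result was seen. Chance could not be excluded for any count. The real split gave 2083 genes at an unadjusted p under 0.05 in limma, and 4 of the 35 splits gave as many, the highest other 3207. For lists called by camera 13 of 35 splits reached the real 18, the highest other giving 28. For DESeq2 4 of 35 splits reached the real 64, the highest other giving 711. The split of vehicle replicates 14 and 33 with PEGPH20 replicate 19 against the rest gave the highest value for each, and 96 genes in limma where the real split gave 0, which points to a structure of the samples other than treatment. The first principal component, 32.3% of the variance, placed those 3 libraries on one side. They had the highest pan-fibroblast levels, 8.51, 9.42 and 8.59 against 7.63 to 8.445 in the rest. Their cell cycle levels were the lowest, 7.43, 7.34 and 7.82 against 7.91 to 8.08. That split thus ran along lists that also differed between PEGPH20 and vehicle.

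The lower pan-fibroblast list with PEGPH20 was not explained by the greater depth of the PEGPH20 libraries, since 101% of its difference was left after thinning every library to the smallest total. At group means of 8.79 and 8.12 that list stood far above the floor, where thinning could move it little. No other list was thinned, neither the matrix and contractile lists nor lists of low level such as the T cell list (3.25 and 3.58). Skin or muscle in the sampled pieces stays open: without PEGPH20 replicates 11 and 37 and vehicle replicate 14 the difference was -0.41 ± 0.50 (SE), and with vehicle replicate 16 left out in place of 14 it was -0.45 ± 0.46. Each comparison kept 1 vehicle piece rich in muscle or keratinocyte transcripts, so neither decides. A candidate explanation is that stroma varied between pieces whatever the treatment. Over 7 libraries the pan-fibroblast level went with the ribosomal list at Pearson's r = -0.91 (exact permutation p = 0.00734, adjusted 0.0294; Spearman's rho = -0.93, permutation p = 0.00675; r = -0.86 without the 2 libraries farthest from the median) and with the cell cycle list at r = -0.74 (exact permutation p = 0.052, adjusted 0.104; rho = -0.86, permutation p = 0.0238), of 4 such relations, the latter resting on the 2 libraries farthest from the median (r = -0.25 without them). Centred within groups these were -0.87 (exact permutation p = 0.0556) and -0.58 (exact permutation p = 0.264), so a varying stroma and an effect of PEGPH20 on the stroma cannot be told apart with 7 tumours.

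The lower keratinocyte list with PEGPH20 rested on vehicle replicate 14, since without it the camera adjusted p was 0.18. Skin epidermis in that piece is a candidate explanation: the ratio of value + 1 to the highest other library was 11.5 in the median of its 15 suprabasal and cornified genes, many of which had no read elsewhere. Krt1, for 1, read 62.8 against 0 in the other 6 libraries, and Flg read 167. Others of that class went the other way: Krt2 read 0, and Ivl read 241 against 402 in PEGPH20 replicate 12. For 9 basal and stress keratinocyte genes the median ratio was 10.6, though Trp63 read 14.8 against 31.7 in PEGPH20 replicate 12. Most of the hair follicle and melanocyte genes had few or no reads in every library and decide nothing, so skin and squamous differentiation of the tumour both stay open. No biological explanation was tested for the keratinocyte list.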
